A study of Citrus sinensis and Citrus x aurantiifolia and Citrus x latifolia with 53 samples.

How the data were processed

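RNA was sequenced from leaves and roots of grafted citrus trees, in 53 libraries, 26 of leaves and 27 of roots. Per the labels, the scions were the diploid Mexican lime (ML) and the triploid Persian lime (PL), and each was grafted on a diploid (2x) or a tetraploid (4x) line of Swingle citrumelo, given in the labels as a cross of Citrus sinensis and Poncirus trifoliata. A combination is written by its scion and the ploidy of its rootstock, so that PL4x is Persian lime on the tetraploid rootstock. Leaves carry the genotype of the scion and roots that of the rootstock. Trees grew for 2 years in 40 L pots before the treatment. The design held 28 trees, with 3 irrigated controls (Ctrl) and 4 trees left without irrigation for 9 days (WD) in each combination, and per the labels leaves and roots came from each tree. Libraries of a group therefore came from separate trees. The files analysed here held all of these except 1 control and 1 water-deficit leaf library and 1 water-deficit root library of PL2x, which were not analysed here. The labels number the libraries within each group, and do not state in words that a number marks the same tree in leaves and roots. In PL2x the missing libraries fall at different places of the numbering in leaves and in roots, so its titles need not mark the same trees, and it was left out of the relation between leaf and root scores.

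Each file held raw read counts per gene, deposited by the authors as whole numbers, not normalised. The reads were trimmed with Trimmomatic and counted with HTSeq, per the submitters' processing notes. Libraries were made with a stranded mRNA kit from 1 µg of total RNA, per the labels' protocols. The aligner, the genome build, the tool versions and the strand setting of the counting are not given in the sources used here. Both tables listed the same 24533 identifiers, of the kind used for the clementine (Citrus clementina) gene models. Reads of a lime or of citrumelo that differ from that reference, or that are shared by near-identical gene copies, can be lost or assigned elsewhere, so a difference between scions in leaves can be a difference in mapping as well as in expression. The files do not pair the identifiers with gene names. The reference table at hand was of another species, sweet orange (Citrus sinensis, assembly DVS_A1.0), and 0 of the 24533 identifiers matched it. The 44 gene lists fixed before the data were examined (drought and hormone pathways, cell type markers and controls) therefore could not be measured, and no cell type marker was tested. Identifiers are given as in the files, at most 2 in each direction for a comparison.

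The total count per library ran from 3747153 to 54838385 in leaves and from 1118899 to 27925992 in roots. The counts of 64 pairs of libraries within groups were compared with a chi-square statistic after scaling to equal totals. Its smallest mean per gene was 16.4, where sampling noise alone gives about 1, so no pair held the same library. Genes were filtered by group with filterByExpr, which kept 19140 genes in leaves and 20452 in roots. Library sizes were scaled by TMM. Each tissue was fitted in edgeR 4.0.16 (R 4.3.3) with its 8 groups, and contrasts were tested with the quasi-likelihood F test (glmQLFit and glmQLFTest, robust). A gene is called where its Benjamini-Hochberg adjusted p is under 0.05, and every adjusted p of a gene is of this test unless another tool is named. If no gene differed, a share of about 0.05 of the genes tested would on average have an unadjusted p under 0.05. Standard errors (SE) are those of the fitted log2 fold change. The biological coefficient of variation common to all genes was 0.38 in leaves and 0.371 in roots. Levels are CPM, counts scaled to a common library total by the TMM factors, as mean ± SD over libraries. A group with no count was set at a floor of 3 counts over the group, which covers counting error only.

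The comparisons fixed before the data were examined were water deficit against control in each combination, the differences of that response between rootstocks (within a scion) and between scions (mean of rootstocks), the 2 rootstocks and the 2 scions in control, the genes called in all 4 combinations, and the overlap of leaf and root calls. Several results were added after the data were examined. They are the mean response of the 4 combinations, the rootstocks compared within each scion or over both treatments, the genes whose libraries do not overlap, the tissue-enriched genes and a water-deficit score. Named identifiers followed a rule fixed in advance, shortened to 2 in each direction because no gene names were at hand. For water deficit they are the highest and lowest mean log2 fold changes over the 4 combinations among genes called in the same direction in all 4, or in at least 3 where fewer qualified, with a mean of at least 1 CPM. For other contrasts they are the highest and lowest among the called genes. Its condition on a known product could not be applied. The gene called by the scion test was the single gene of that test.

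The water-deficit score places each library along the mean response of its tissue. The axis is the mean over the 4 combinations of the difference of mean log2 CPM (prior count 2) between water-deficit and control libraries, over all tested genes. A library's projection on it is given relative to the control mean of its combination, in percent of the mean response. Control groups therefore average 0 and the 4 water-deficit means average 100 by construction. Since this axis includes the libraries scored, which moves them along it, scores were also computed on an axis from the other 3 combinations. Differences of response were tested by permuting labels exactly within strata, two-sided, with 6 tests adjusted together. Rootstock or scion labels were permuted among controls and among water-deficit libraries alike. The p-values therefore assume no rootstock or scion effect in controls either, and do not test the difference of response alone. Tissue-enriched genes had a mean over all libraries at least 16-fold above that of the other tissue, 796 genes in leaves and 1429 in roots. They were tested with camera in limma 3.58.1, with 20 tests per tissue adjusted together. They were chosen on these libraries and are not independent evidence.

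The test was tried on simulated data with few changed genes, using real means and depths and the same fitted spread in all groups. In ML2x leaves it called 12% of 100 genes with a 2-fold change and 82% of 100 with a 4-fold change, and in PL2x leaves 3% and 64%. In roots the shares were 12% and 71% for ML2x, and 5% and 76% for PL2x. Between 0 and 3 unchanged genes were called in each of these. The alternatives chosen before the data were examined were DESeq2's size factors in edgeR, no low-count filter, DESeq2 1.42.0, limma's voom with quality weights per library, a fit on the compared libraries alone, the replicate number as a block, and leaving out each library in turn. Leaving out the 3 libraries with the fewest counts was added after the data were examined.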

Results

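The study asked whether a tetraploid rootstock or a triploid scion changes how a grafted lime tree responds to lack of water. Leaves and roots were sequenced from 4 combinations of scion and rootstock, irrigated or after 9 days without irrigation. Each control group held 3 libraries and each water-deficit group 4, except PL2x, which had 2 control and 3 water-deficit leaf libraries and 3 water-deficit root libraries. Total counts per library ran from 3747153 to 54838385 in leaves and from 1118899 to 27925992 in roots. The 3 libraries with the fewest counts were PL2x Ctrl 1 (3747153) and ML2x WD 3 (4785434) of leaves and ML2x WD 4 (1118899) of roots.

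In leaves, lack of water changed a large share of the transcriptome. Over the mean of the 4 combinations 5325 genes rose and 3891 fell among 19140 tested, and 3444 of these changed more than 2-fold. Ciclev10002949m.g rose from 4.04 ± 3.22 CPM in the 11 control libraries to 241 ± 184 CPM in the 15 water-deficit libraries, a mean log2 fold change of 5.66 ± 0.71 (SE, adjusted p = 1.2e-05). Ciclev10008812m.g rose from 9.31 ± 3.55 to 318 ± 233 CPM (log2 4.81 ± 0.51, adjusted p = 6.8e-06). Ciclev10005306m.g fell from 10.4 ± 8.95 to 1.26 ± 1.5 CPM, and Ciclev10012001m.g from 12.8 ± 9.92 to 1.57 ± 2 CPM.

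The most abundant leaf transcripts took a smaller mean share of the counts under water deficit in each combination. The 10 genes with the highest mean level took 11.7 ± 0.777% of the counts in ML2x controls, 12.6 ± 0.569% in ML4x, 12.4 ± 0.212% in PL2x and 13.2 ± 0.656% in PL4x controls. Under water deficit they took 4.76 ± 1.1%, 7.96 ± 2.83%, 8.82 ± 4.15% and 4.22 ± 3.25% in the same order (SD, n = 2 to 4), though libraries ML4x WD 1 at 11.8% and PL2x WD 1 at 11.7% stood at the level of controls. Of these 10 genes 7 fell and 0 rose in the mean response by edgeR's test. Of the 796 leaf-enriched genes, chosen on these libraries and so not independent evidence, 443 fell, 77 rose and 276 were not called in the mean response, with a median log2 fold change of -0.64 against 0.11 for the other genes. Adjusted over the list alone, 450 fell and 86 rose. Camera's preset correlation placed the set below the other genes (adjusted p = 4.2e-16), but the call was lost with an estimated correlation (adjusted p = 0.64). The root-enriched genes measured in leaves went both ways, with 182 higher and 135 lower of 745.

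The number of leaf genes called by edgeR differed widely between combinations, and the size of the gap depended on the tool. In ML2x 1140 genes rose and 1024 fell, in ML4x 57 rose and 49 fell, and in PL4x 3170 rose and 2347 fell. DESeq2 called 3290 in ML2x, 793 in ML4x and 6196 in PL4x, and voom 7100, 6269 and 9306. At an unadjusted p under 0.05 edgeR had 5640, 3660 and 7972 genes in the same order. Ciclev10002949m.g rose in ML2x (log2 7.22 ± 1.34, SE, adjusted p = 0.0066), in ML4x (5.67 ± 1.24, adjusted p = 0.048) and in PL4x (6.61 ± 1.31, adjusted p = 0.002), and stood at 3.14 ± 1.38 in PL2x (adjusted p = 0.18). The excess of higher genes in PL4x was not kept with DESeq2's size factors in edgeR (2647 higher, 2705 lower). In PL2x edgeR called 0 genes, with 4493 at an unadjusted p under 0.05, while DESeq2 called 1770 and limma's voom with quality weights 3455. Leaving out PL2x WD 1 raised the PL2x count to 1883, and leaving out PL2x Ctrl 1 or Ctrl 2 gave 4 and 14, with the lone control assumed to vary like the other groups. The ML2x count fell to 65, 432 or 158 without Ctrl 1, 2 or 3 and to 733, 964 or 858 without WD 2, 3 or 4; the ML4x count became 0 without any 1 of its controls or without WD 3 or WD 4, 20 without WD 2 and 502 without WD 1; and the PL4x count fell to 3117 without Ctrl 1 and 3231 without WD 4.

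The called genes overlapped between combinations beyond the number that independent lists would share. ML2x and PL4x shared 791 higher genes, where independent lists would share 189, and 644 lower genes (126 for independent lists), with 2 and 1 genes called in opposite directions. Of the 57 genes that rose in ML4x, 51 also rose in ML2x and 47 in PL4x. At least 3 combinations shared 45 higher and 17 lower genes, against 0.562 and 0.321 for independent lists. Because PL2x had 0 calls by edgeR, 0 leaf genes were called in all 4 combinations, while DESeq2 placed 95 there (72 higher, 23 lower) and voom 676 (305 higher, 371 lower). Across genes, which are not independent replicates, log2 fold changes of 2 combinations correlated between 0.317 (ML2x and PL2x) and 0.708 (ML2x and PL4x).

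**Figure D1:**
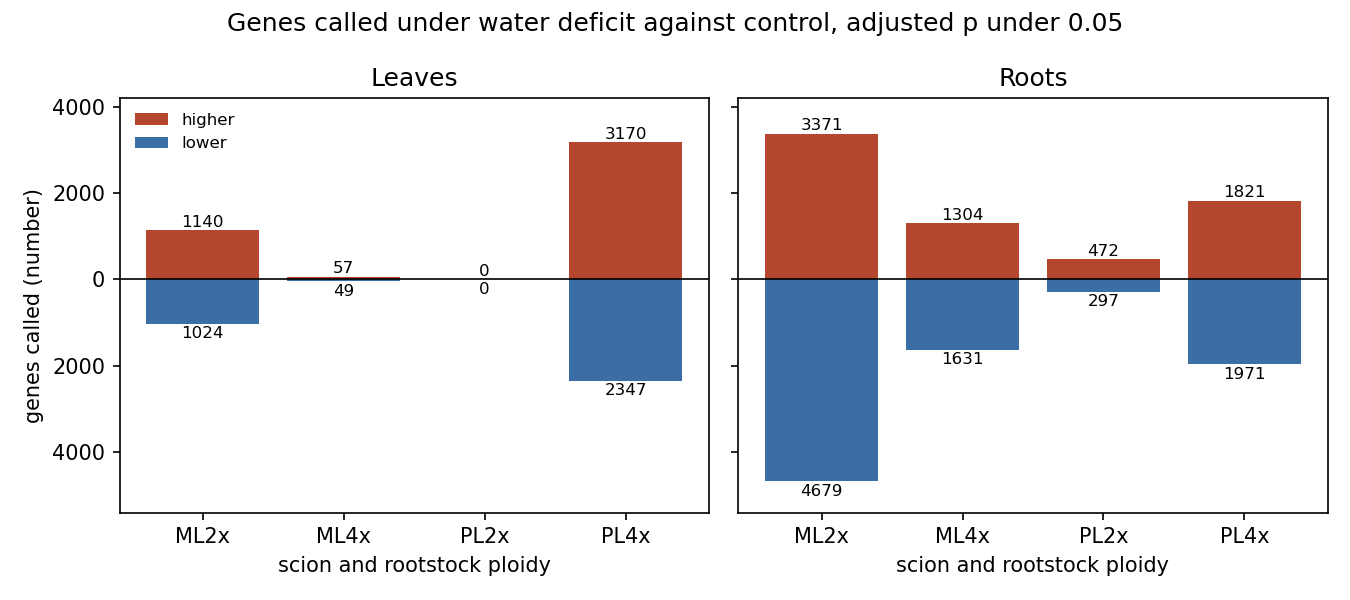
Numbers of genes called higher (red, above 0) and lower (blue, below 0) under water deficit against control at an adjusted p under 0.05 in edgeR, for each scion and rootstock ploidy in leaves (left) and roots (right). Counts run from 0 in PL2x leaves to 3371 higher and 4679 lower in ML2x roots.

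In roots, lack of water also changed a large share of the genes. Over the mean of the 4 combinations 5574 genes rose and 6282 fell among 20452 tested, and falls over 2-fold (3487 genes) outnumbered such rises (1234). Ciclev10006437m.g rose from 1.06 ± 0.601 CPM in 12 control libraries to 74.9 ± 36.3 CPM in 15 water-deficit libraries (log2 6.24 ± 0.38, SE, adjusted p = 7.3e-10), and passed the test in each combination. Ciclev10005699m.g rose from 0.11 ± 0.123 to 8.96 ± 8.06 CPM. It had 0 counts in the ML4x controls and ranged from 0.358 to 27.9 CPM in the ML4x water-deficit roots. Ciclev10029991m.g fell from 135 ± 140 to 0.557 ± 1.58 CPM and Ciclev10017587m.g from 46 ± 38.7 to 0.424 ± 0.931 CPM.

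Among genes enriched in roots over leaves, chosen on these libraries and so not independent evidence, more fell than rose in roots. Of these 1429 genes 780 fell, 238 rose and 411 were not called in the mean response, with a median log2 fold change of -0.73 against 0.01 for the other genes. Adjusted over the list alone, 795 fell and 244 rose. The preset correlation in camera gave adjusted p = 1.5e-06, and the call was lost with an estimated correlation (adjusted p = 0.56). Of the 553 leaf-enriched genes measured in roots, 132 rose and 113 fell.

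Root calls were most numerous on the diploid rootstock under Mexican lime. ML2x roots had 3371 higher and 4679 lower genes, ML4x 1304 and 1631, PL2x 472 and 297, and PL4x 1821 and 1971. Ciclev10029991m.g fell from 283 ± 234 to 0.0319 ± 0.0372 CPM in ML2x, from 72.5 ± 53.6 to 0.274 ± 0.384 in ML4x, from 110 ± 16.8 to 2.17 ± 3.51 in PL2x and from 76.4 ± 75.9 to 0.159 ± 0.236 in PL4x (SD, n = 3 or 4). Higher genes made up 61.4% of the PL2x calls in edgeR, whereas DESeq2 called 721 higher and 833 lower there and voom 3968 and 4257. Single libraries moved these counts: ML4x fell to 1789 or 1552 without Ctrl 2 or 3 and to 1415 without WD 3; PL2x fell to 401, 117 or 418 without Ctrl 1, 2 or 3 and to 179 or 302 without WD 1 or 2, and rose to 1224 without WD 3. PL4x fell to 1945 or 2025 without Ctrl 1 or 3 and to 2054 or 2059 without WD 3 or 4, and rose to 6905 without WD 2.

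A common root response was shared by the 4 combinations. All 4 called 302 higher and 173 lower genes in edgeR, where independent lists would share 0.442 and 0.522. DESeq2 placed 434 higher and 448 lower genes there, and voom 1374 and 1744. Ciclev10006437m.g was among the higher ones, at log2 5.67 ± 0.73 in ML2x, 6.72 ± 0.8 in ML4x, 5.96 ± 0.75 in PL2x and 6.6 ± 0.78 in PL4x (SE). Of the 297 genes that fell in PL2x, 276 also fell in ML2x. Log2 fold changes of 2 combinations correlated across genes between 0.731 (ML2x and ML4x) and 0.853 (ML2x and PL4x).

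Leaves and roots shared part of their response. Of the 18179 genes tested in both, 2493 rose in both tissues in the mean response and 1729 fell in both, where independent lists would give 1520 and 997. Opposite calls were fewer than independent lists would give, with 671 genes higher in leaves and lower in roots (1410) and 495 lower in leaves and higher in roots (1080). In PL4x 752 genes rose and 355 fell in both tissues (295 and 172 for independent lists), and in ML2x 364 rose and 384 fell (199 and 191). ML4x had 20 and 16 such genes (3.79 and 3.24) and PL2x had 0 of either, having 0 leaf calls by edgeR. Across these genes the leaf and root fold changes of the mean response correlated at 0.337.

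No gene passed edgeR's test for a response to lack of water that differed between diploid and tetraploid rootstocks, in either scion or tissue. In ML leaves 0 genes were called (623 at an unadjusted p under 0.05, 0 by DESeq2, 0 by voom) and in PL leaves 0 (1977 unadjusted, 69 by DESeq2, 5004 by voom). In ML roots 0 were called (2915 unadjusted, 269 by DESeq2, 58 by voom) and in PL roots 0 (653 unadjusted, 1 by DESeq2, 80 by voom). Against the share of 0.05 that chance alone gives on average, the unadjusted counts were lower in ML leaves and PL roots. They were higher in PL leaves and ML roots. Leaving out PL4x WD 2 gave 1823 calls in PL leaves, and leaving out PL2x Ctrl 1 or Ctrl 2 gave 1 or 25. In ML roots 38 genes were called without ML2x WD 1, 24 without ML2x Ctrl 3, 8 without ML4x WD 4 and 1 without ML4x Ctrl 2.

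Scored along the whole response, the mean scores of the rootstocks ranked in opposite order under the 2 scions. No rootstock difference passed its test after adjustment, and whether these differences themselves differed between scions was not tested. In roots the water-deficit score was 136.4 ± 27.8% in ML2x and 86.3 ± 38.1% in ML4x (SD, n = 4), and 76.3 ± 40.9% in PL2x (n = 3) and 101 ± 36.9% in PL4x (n = 4). The difference of response between ML4x and ML2x roots was -50.1 points (exact permutation p = 0.0457, adjusted p = 0.274 over 6 tests), and that between PL4x and PL2x roots 24.6 points (exact permutation p = 0.46). Before subtraction of the controls, ML4x minus ML2x was -34 points in water-deficit roots and 16.1 in control roots, the first minus the second being the difference of response. PL4x minus PL2x was 34.9 points in water-deficit roots and 10.3 in control roots. In leaves the scores were 102.1 ± 16.5% in ML2x, 75.2 ± 33.8% in ML4x, 89.7 ± 57.8% in PL2x and 133 ± 35.7% in PL4x, with differences of -26.8 points in ML (exact permutation p = 0.276) and 43.4 points in PL (exact permutation p = 0.317). Spread was wider under water deficit: the pooled SD was 36.6 points against 15.3 in control leaves (permutation p = 0.0048, one-sided) and 35.8 against 10.7 in roots (permutation p = 0.00041, one-sided). On an axis from the other 3 combinations the score of leaf library PL2x WD 1 was 8.37%, against 35.6% on the axis that includes it, and 0.584 control SDs above its control mean; the next lowest was ML4x WD 1, at 2.05 control SDs in leaves and 2.32 in roots. Single libraries moved these differences: without ML4x WD 1 the ML root difference was -31.1 points (exact permutation p = 0.113), and the ML leaf difference was -14.4 without ML4x WD 1 and -16.9 without ML4x WD 2. The PL leaf difference was 12.9 without PL2x Ctrl 2, 13.4 without PL2x WD 1, 76 without PL2x WD 2 and 68.5 without PL4x WD 2, and the PL root difference 5.06 without PL2x WD 3, 48 without PL2x WD 1 and 41.9 without PL4x WD 2. On an axis from the other scion alone the ML leaf difference was -10.8 points (exact permutation p = 0.556).

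**Figure D2:**
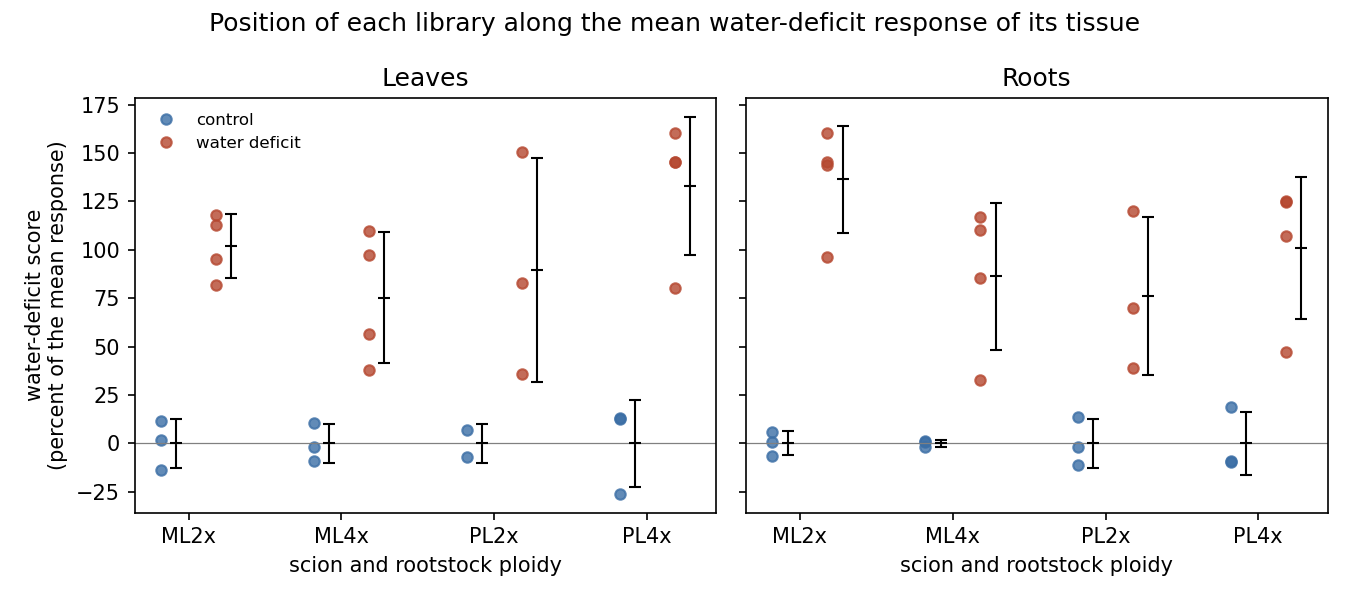
Water-deficit score of each library, in percent of the mean response of its tissue (vertical axis), by scion and rootstock ploidy in leaves (left) and roots (right). Blue points are control libraries, red points water-deficit libraries, and bars beside them the mean ± SD; control means are 0 by construction. On this axis, which includes the libraries shown, every water-deficit library stands above the controls of its combination, from 35.6% upward in leaves and 32.9% upward in roots, while no control exceeds 13.2% in leaves or 18.7% in roots.

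In leaves 1 gene passed edgeR's test for a response that differed between the scions, and 2 of 30 splits of the libraries, the real one included, gave as many calls. Ciclev10016655m.g went from 2.77 ± 0.435 to 7.8 ± 2.48 CPM under water deficit in ML2x leaves and from 4.09 ± 0.643 to 9.88 ± 4.02 CPM in ML4x, and from 6.28 ± 0.0349 to 3.29 ± 0.102 CPM in PL2x and from 8.71 ± 2.68 to 4.81 ± 0.481 CPM in PL4x (SD, n = 2 to 4). Its response was lower in Persian than in Mexican lime by -2.28 ± 0.32 on the log2 scale (SE, adjusted p = 0.008). Without the 2 leaf libraries of fewest counts the difference was -2.29 ± 0.35 and the call was lost (adjusted p = 0.052). DESeq2 called 146 genes and voom 619, and leaving out PL4x WD 2 gave 64, ML4x WD 1 gave 7, PL4x Ctrl 2 gave 4, ML2x WD 1 or PL2x Ctrl 2 gave 3 and ML2x WD 3, PL2x WD 1 or PL4x Ctrl 3 gave 2. In roots, whose genotype is the rootstock's, 0 genes were called (660 at an unadjusted p under 0.05, 0 by DESeq2, 0 by voom). The scores differed by 22.7 points between Persian and Mexican lime in leaves (exact permutation p = 0.389) and by -22.7 points in roots (exact permutation p = 0.293). The leaf value was 10.7 without PL2x WD 2, 13.1 without PL4x Ctrl 1, 13.5 without ML4x WD 1, 34.3 without PL2x WD 1 and 35.6 without PL2x Ctrl 2, and the root value -12.4 without PL2x WD 3, -12.5 without PL4x WD 2 and -35.2 without PL2x WD 1.

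Irrigated roots differed between the rootstocks, while no gene passed edgeR's test in irrigated leaves. In roots 156 genes were higher and 467 lower on the tetraploid rootstock, 436 of them by more than 2-fold. Ciclev10003082m.g stood at 5.17 ± 0.583 CPM in the 6 tetraploid control libraries and 0.0704 ± 0.155 CPM in the 6 diploid ones, and Ciclev10020909m.g at 4.12 ± 1.99 and 0.163 ± 0.129 CPM (SD). Ciclev10022680m.g was lower, at 0.319 ± 0.414 against 14.1 ± 14.4 CPM, as was Ciclev10021923m.g, at 0.556 ± 0.697 against 22.2 ± 32.4 CPM. In leaves 0 genes were called (392 at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom, 1 without PL2x Ctrl 1). The root count fell to 292 without ML2x Ctrl 1, 324 without PL2x Ctrl 2 and 390 without PL4x Ctrl 2.

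The rootstock difference in control roots was counted mainly under Mexican lime, although the scions were not shown to differ in it. Under Mexican lime 83 genes were higher and 355 lower on the tetraploid, and under Persian lime 1 gene was called, Ciclev10003082m.g, at 4.96 ± 0.682 CPM in tetraploid and 0.0127 ± 0.022 CPM in diploid controls (SD, n = 3). The test of the difference between scions called 0 genes in edgeR (357 at an unadjusted p under 0.05; DESeq2 and voom were not run on it). Over both treatments and scions 301 genes were higher and 619 lower on the tetraploid. For 4 genes, among them Ciclev10003082m.g and Ciclev10020909m.g, each of the 14 tetraploid root libraries stood above each of the 13 diploid ones, where 100 permutations within scion and treatment gave at most 0 such genes. Across all libraries Ciclev10003082m.g ranged from 3.01 to 6.59 CPM in tetraploid roots and reached at most 1.09 CPM in diploid roots.

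The scions differed in irrigated leaves, and not past the test in irrigated roots. In leaves 1183 genes were higher and 1192 lower in Persian than in Mexican lime, 1312 of them by more than 2-fold. Ciclev10013227m.g was at 41.6 ± 10.2 CPM in 5 Persian lime control libraries and had 2 counts in all 6 Mexican lime ones together, and Ciclev10025396m.g was at 20.7 ± 8.44 CPM against 3 counts. Ciclev10003420m.g was at 2.99 ± 0.636 CPM in Mexican lime and had 0 counts in Persian lime controls, at least 66-fold lower by the floor of 3 counts over the group, and Ciclev10033176m.g was at 12.5 ± 2.34 CPM against 2 counts. In roots 0 genes were called (790 at an unadjusted p under 0.05, 0 by DESeq2, 1 by voom). The leaf count moved to 981 without PL2x Ctrl 1, 1544 without PL2x Ctrl 2, 1372 without PL4x Ctrl 1, 1273 or 1297 without ML2x Ctrl 2 or 3 and 1289 or 1547 without ML4x Ctrl 1 or 2, and the species of the scion, its ploidy and its match to the clementine gene models differ together.

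Within ML2x, ML4x and PL4x, leaf and root scores of same-numbered water-deficit libraries were correlated. Over these 12 libraries per tissue the relation did not pass the test without 2 of them. With PL2x it changed with the pairing and the libraries left out. Levels of a pair differed, as for ML4x WD 2 at 56.3% in leaves and 110% in roots. The relation was computed over 12 water-deficit libraries per tissue, of ML2x, ML4x and PL4x, after centring on the mean of each combination, with Pearson's r = 0.82 (exact permutation p = 0.0097, adjusted p = 0.019 over 2 relations) and Spearman's rho = 0.751 (exact permutation p = 0.027). Uncentred, r was 0.591 (permutation p = 0.042) and rho 0.58 (permutation p = 0.052). Without the 2 libraries farthest from the median, ML4x WD 1 and PL4x WD 2, the centred r over 10 libraries was 0.43 (exact permutation p = 0.31). The uncentred r with its own 2 farthest left out was 0.377. The centred relation thus did not pass the test without those libraries. Within single combinations r was 0.874 in ML2x, which holds neither of them, 0.668 in ML4x and 0.977 in PL4x. Each of these is over 4 libraries and was not tested. In 9 control libraries the centred r was 0.491 (exact permutation p = 0.49). PL2x was left out because its library numbers skip different places in leaves and roots. With PL2x paired by title number the centred r over 15 libraries was 0.356 (exact permutation p = 0.3, rho = 0.313, exact permutation p = 0.36). Pairing by the place of the library number added only 2 PL2x libraries, which fall on a line once centred, whatever their scores. That pairing gave a centred r of 0.861 over 14 libraries (exact permutation p = 0.0048, rho = 0.842, exact permutation p = 0.0086). Without the 2 farthest libraries of each, r was 0.7 by title number (exact permutation p = 0.037) and 0.712 by place (exact permutation p = 0.16), and over the 3 pairings the adjusted p was 0.015 without PL2x, 0.3 by title number and 0.014 by place. On an axis from the other 3 combinations the centred r over the 12 libraries was 0.735 (exact permutation p = 0.03) and rho 0.625 (exact permutation p = 0.09).

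**Figure D3:**
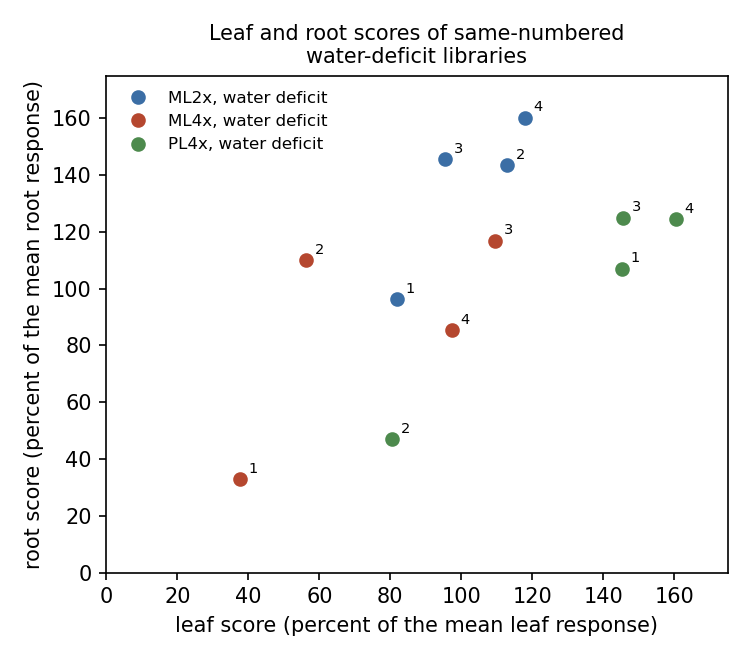
Leaf score (horizontal axis) against root score (vertical axis) of same-numbered water-deficit libraries of ML2x (blue), ML4x (red) and PL4x (green), each in percent of the mean response of its tissue. ML4x WD 1 lies lowest in both tissues, at 37.7% in leaves and 32.9% in roots, and PL4x WD 2 is the lowest of PL4x in both, at 80.5% and 47%.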

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

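The tests of whether trees dried to different degrees, of control libraries labelled as water deficit and of the position of control roots on the water-deficit axis were chosen after the results were seen, as were the pairings that include PL2x, the scores on an axis from the other 3 combinations, the water-deficit score, the mean over the 4 combinations and the rootstock comparison over both treatments. The search for single libraries that stand apart was limited, after a wider search. It kept measures of each library and the identifiers named for water deficit or for the scion's response to it.

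In leaves, Ciclev10005306m.g stood at 0.724 CPM in ML2x WD 3 against 0.043 to 0.118 CPM in the other 3 libraries of its group, and at 5.96 CPM in PL4x WD 2 against 0.784 to 1.51 CPM. In roots, Ciclev10017587m.g stood at 1.27 CPM in ML4x WD 1 against 0 to 0.116 CPM, and at 0.0576 CPM in ML2x WD 1, a count near the floor, against 0 in the others. These 4 values stood out by Dixon's test among 51 groups of 4 values, where chance marks about 5% if values are normal. Low CPM need not be normal, and a lone count against 0 in the others is marked whatever its size. Chance is therefore not excluded for these values. The 51 cover the total count, the genes with a count, the share of the 10 most abundant genes and the score of each group, besides the identifiers named for water deficit and for the scion's response to it. The response of Ciclev10016655m.g to water deficit in leaves differed between the scions by -2.28 on the log2 scale.

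The water-deficit libraries of a combination lay far apart along the mean response, with PL2x WD 1 and ML4x WD 1 lowest in leaves and ML4x WD 1 lowest in roots. Depth was argued against, since with all libraries thinned to the smallest total of their tissue the deviations from group means correlated with those at full depth at 0.999 in leaves and 0.971 in roots. Of the 15 libraries of either tissue 0 stood at or below the highest control of its combination, but that axis includes them: on an axis from the other 3 combinations PL2x WD 1 of leaves scored 8.37% (highest control 2.97%, pooled control SD 14.3). Its named identifiers went both ways, with Ciclev10002949m.g at 2.42 CPM and Ciclev10008812m.g at 9.29 CPM among the PL2x controls (1.98 to 12.2 and 6.25 to 17 CPM), Ciclev10012001m.g overlapping them (0.0726 to 7.57 CPM in the 3 water-deficit libraries against 3.28 to 14.3 CPM), and Ciclev10005306m.g (0.508 to 2.44 CPM against 10.1 to 33.8 CPM) and Ciclev10016655m.g (3.18 to 3.38 CPM against 6.26 to 6.31 CPM) clear of them, so with 2 controls a wrong label stays open for it. These identifiers had been chosen on contrasts that counted PL2x WD 1 as water deficit, so their levels are not independent evidence on its label. Trees that dried to different degrees in 9 days stay open as an explanation that may apply. Leaf and root scores of 1 number correlated over 12 libraries (r = 0.82, exact permutation p = 0.0097). Without ML4x WD 1 and PL4x WD 2 the relation did not pass the test (r = 0.43, exact permutation p = 0.31). Within ML2x, which holds neither of them, r was 0.874 over 4 libraries and was not tested. With PL2x the relation changed with the pairing and with the libraries left out. By title number r was 0.356 (exact permutation p = 0.3) and 0.7 without the 2 farthest (exact permutation p = 0.037). Pairing by the place of the library number added only 2 PL2x libraries, which fall on a line once centred. It gave 0.861 (exact permutation p = 0.0048) and 0.712 without the 2 farthest (exact permutation p = 0.16).

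Control roots of the 2 rootstocks differed in 623 genes. Depth as the whole cause was argued against, since thinning every root library to 7051006 counts without the smallest library left 685 called genes against 792 before thinning. Control roots on the tetraploid rootstock stood 12.9 points higher on a water-deficit axis from the other scion's libraries (17.1 under Mexican and 8.74 under Persian lime, exact permutation p = 0.035 over 400 relabelings). In control leaves the same difference was -4.54 points (-7.57 under Mexican and -1.5 under Persian lime, exact permutation p = 0.36). Neither p-value was adjusted. A difference in water status of the control trees could account for part of the difference in root genes, though the leaf value had the opposite sign. The best move along the root axis held 5.79% of the squared log2 differences of the called genes (1.81% under Mexican and 9.77% under Persian lime). Of these genes 57.5% under Mexican and 66.9% under Persian lime had the sign of the water-deficit response. Differences within a scion carry noise, and the share that noise would leave was not computed. A move along the axis as the whole difference is therefore argued against only weakly. The ploidy of the rootstock, which the design names, stays open beside other differences between the 2 rootstock lines, which the labels do not separate from ploidy.

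PL2x leaves gave 0 called genes in edgeR (4493 at an unadjusted p under 0.05, 1770 by DESeq2, 3455 by voom) and PL4x leaves 5517. Fewer libraries in PL2x could account for part of this. Over the 12 subsets of PL4x with 2 controls and 3 water-deficit libraries the median count was 3198, the fewest 721 and the most 6980. The count of 0 depended on PL2x WD 1, since without it, with still fewer libraries, 1883 genes were called, while 4 were called without the control of 3747153 counts and 14 without the other control. How much of the remaining distance to PL4x comes from the number of libraries or from the rootstock stays open, and the test of a different response between rootstocks called 0 genes in edgeR (1977 at an unadjusted p under 0.05, 69 by DESeq2, 5004 by voom, and 1823 without PL4x WD 2, 25 without PL2x Ctrl 2 and 1 without PL2x Ctrl 1).

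Counts were compared with those from other splits of the same libraries. For ML2x, 1 of 35 splits, the real one, gave as many genes in leaves (2164, highest other 1712) and in roots (8050, highest other 5921). This is the smallest share that 35 splits can give and was not adjusted over the comparisons, so chance is argued against but not excluded. For ML4x, 2 of 35 splits did in leaves (106, highest other 363) and in roots (2935, highest other 3739), and for PL4x 2 of 35 in leaves (5517, highest other 7238) and in roots (3792, highest other 7057), so chance is not excluded by this count. In each of these 6 cases the highest other split set the 3 controls and 1 water-deficit library, WD 1 in ML2x and ML4x and WD 2 in PL4x, against the other 3 water-deficit libraries. It thus kept most of the treatment labels apart, and the median of the other splits was 0. ML4x WD 1 and PL4x WD 2 had the lowest scores of their groups in both tissues. Overlaps with combinations that share no library argue against unrelated lists for ML4x and PL4x. They do not tell the real labels from a split that keeps most of them, since overlaps of other splits were not computed. ML4x leaves shared 51 of 57 rises with ML2x (3.39 for independent lists) and PL4x leaves 791 (189). ML4x and PL4x roots shared 894 rises (116), and falls were likewise shared beyond independent lists. For PL2x roots the 10 splits are too few for a share under 0.05 (769, highest other 0).

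No splits were counted for PL2x leaves or for the response between rootstocks in PL leaves, since PL2x had 2 leaf controls. Among 30 splits drawn for each of the other comparisons, the real one alone gave as many genes for the mean over the 4 combinations in leaves (9216, highest other 1309) and roots (11856, highest other 7), the scions in control leaves (2375, highest other 1), the rootstocks in control roots (623, highest other 0) and the rootstocks over both treatments in roots (920, highest other 739). This argues against chance for these 5 but does not exclude it. It is the smallest share that 30 splits can give, and it was not adjusted over the comparisons. For the 1 gene of the scion's response in leaves 2 of 30 splits gave as many (highest other 2), so chance is not excluded. For the other 7 comparisons, in which edgeR called 0 genes, 30 of 30 splits gave as many, as any splits must against a count of 0, so this number says nothing of chance. The highest others were 0 and 515 for the response between rootstocks in ML leaves and ML roots, 1253 in PL roots, 388 for the response between scions in roots, 79 for the rootstocks in control leaves, 1787 for the rootstocks over both treatments in leaves and 1 for the scions in control roots. The rootstock comparison over both treatments in leaves had 587 genes at an unadjusted p under 0.05, 0 calls by DESeq2 and 19 by voom, and 1 call without PL2x Ctrl 2 or PL4x WD 2. Splits that called many genes where the real one called 0 point to a structure of the samples.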

How the results depend on the processing

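Leaving out the 3 libraries with the fewest counts, the estimated correlation and every alternative of the scores and of their relation between tissues, the tissue-enriched sets, the mean over the 4 combinations and the rootstock comparison over both treatments were chosen after the results were seen. Among named fold changes, scores, their relation between tissues and medians of tissue-enriched sets in linear fits of log2 CPM (-0.7 in leaves and -0.87 in roots) 0 reversed in sign, but the larger of the higher and lower counts did change for several comparisons, given last. Of 449 alternatives of the 17 named fold changes, 448 stayed past the threshold, and the exception was Ciclev10016655m.g without the leaf libraries of fewest counts (-2.29, adjusted p = 0.052). For water deficit these were fold changes of the mean over the 4 combinations, and those within single combinations were not followed. The named calls in ML4x leaves were lost wherever that count became 0. The 17 had been chosen among called genes for extreme fold changes, which favours such an outcome. Of 140 alternatives of the 21 planned counts that left out no single library, 91 were within 1.5 times and 49 beyond. Of 122 alternatives of the scores 0 reversed and 8 had an exact permutation p under 0.05. The fixed gene lists under water deficit gave no values and their alternatives were not run, since no identifier matched the reference table. Where a count moved, the cause was not tested, except that fewer libraries were fitted where libraries were left out or only those compared were used.

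In leaves, DESeq2 called 3290 genes under water deficit in ML2x, 793 in ML4x and 1770 in PL2x, 95 in all 4 combinations, 69 for the rootstock's response in PL, 146 for the scion's response and 1 between rootstocks in control. Voom with quality weights called 7100 in ML2x, 6269 in ML4x, 3455 in PL2x and 9306 in PL4x, 676 in all 4, 5004 for the rootstock's response in PL, 619 for the scion's response and 3838 between scions in control. DESeq2 size factors gave 2 genes for the scion's response, and no low-count filter gave 47 in ML4x. A fit on only the compared libraries gave 0 in ML4x (3660 at an unadjusted p under 0.05 in the edgeR fit of all libraries), 1134 in PL4x and 3662 between scions. Without the libraries of fewest counts ML2x gave 838, ML4x 60, PL2x 6, the rootstock's response in PL 1, the scion's response 0 (edgeR; 2775 at an unadjusted p under 0.05 with all libraries), the rootstocks in control 2 and the scions in control 1179.

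In roots, DESeq2 called 1554 genes in PL2x, 882 in all 4 combinations, 269 and 1 for the rootstock's response in ML and PL and 1204 between rootstocks in control. Its overlaps of leaf and root calls in the same direction, summed over the 4 combinations, came to 2961. A gene counts there once for each combination that shares it. Voom called 5903 in ML4x, 8225 in PL2x, 10253 in PL4x, 3118 in all 4, 58 and 80 for the rootstock's response in ML and PL, 2900 between rootstocks and 1 between scions in control. A fit on only the compared libraries gave 1787 in ML4x, 426 in PL2x, 1218 in PL4x and 1111 between rootstocks.

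With the replicate number as a block, leaves gave 822 genes in ML2x and 0 in ML4x by edgeR (3660 at an unadjusted p under 0.05 without the block), and roots gave 2472 in PL4x and 314 in all 4 combinations. The numbers did not pair the libraries, since 6 of 23 controls were closest to the water-deficit library of their own number.

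Leaving out 1 library at a time moved the leaf counts between 65 and 2977 in ML2x, 0 and 502 in ML4x, 0 and 1883 in PL2x and 3117 and 7680 in PL4x. The range was 0 to 1823 for the rootstock's response in PL, 1 to 64 for the scion's response, 0 to 1 for the rootstocks in control and 981 to 3100 for the scions in control. In roots it was 5620 to 8648 in ML2x, 1415 to 4229 in ML4x, 117 to 1224 in PL2x, 1945 to 6905 in PL4x, 0 to 38 for the rootstock's response in ML and 292 to 680 for the rootstocks in control. In the simulated data 12% of genes with a 2-fold change were called in ML2x leaves and 3% in PL2x leaves. Few genes were changed there and every group had the same spread, so these shares need not hold for the real comparisons. In ML2x roots 5458 of the 8050 called genes changed more than 2-fold, so others were called at smaller changes.

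The majority of called genes turned from higher to lower in PL4x leaves with DESeq2 size factors (2647 higher, 2705 lower), in ML2x leaves with voom (3410, 3690), only the compared libraries (1338, 1793) or without Ctrl 2 (214, 218), in ML4x leaves with voom (3045, 3224), and in PL2x roots (721, 833) and all 4 combinations in roots (434, 448) with DESeq2, as with voom (3968, 4257 and 1374, 1744). It turned from lower to higher in roots without the library of fewest counts in ML4x (1901, 1880) and PL4x (2344, 2166), and in PL4x without WD 1 (1590, 1429). Between scions in control leaves, 1183 higher and 1192 lower, it turned to higher under DESeq2 size factors (1270, 1126), no filter (1056, 1032), voom (1920, 1918), only the compared libraries (2054, 1608), without the libraries of fewest counts (767, 412) and without any 1 of ML2x Ctrl 2 or 3, ML4x Ctrl 1 or 2, PL2x Ctrl 1 and PL4x Ctrl 1.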

Other observations

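The counts of genes whose libraries do not overlap and the tissue-enriched sets were chosen after the results were seen. In leaves 190 genes separated the scions completely, with each of 12 Persian lime libraries above each of 14 Mexican lime libraries for 146 genes and below for 44, where 100 permutations gave at most 0. Of these, 34 had a mean under 0.1 CPM in Mexican lime and over 1 CPM in Persian lime, and 4 the reverse. Ciclev10013227m.g in control leaves was at 41.6 ± 10.2 CPM in Persian lime and 0.0294 ± 0.0467 CPM in Mexican lime (SD, n = 5 and 6). By rootstock 0 leaf genes and 4 root genes separated in this way, and by scion 0 root genes; these counts rest on ranks, not on edgeR.

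The fall of tissue-enriched genes differed in count between combinations. For the difference between scions in leaves edgeR called 1 leaf-enriched gene, Ciclev10016655m.g (2 adjusted over the list alone), and for that between rootstocks in ML roots it called 0 of all genes (2915 at an unadjusted p under 0.05, 269 by DESeq2, 58 by voom) and 12 root-enriched genes, all with a higher log2 fold change under water deficit on the tetraploid, when adjusted over the list alone. In leaves 356 of 796 leaf-enriched genes fell and 52 rose in PL4x, 135 fell and 38 rose in ML2x, and 2 fell and 2 rose in ML4x. Of all genes tested, 28.8% were called in PL4x, 11.3% in ML2x and 0.554% in ML4x, so these counts depend on the calls of each combination. In PL2x leaves edgeR called 0 genes in all (4493 at an unadjusted p under 0.05, 1770 by DESeq2, 3455 by voom), so 0 of the leaf-enriched set. The median log2 fold change of that set lay below that of the other genes in each combination. It was -1 against 0.15 in PL4x, -0.65 against 0.09 in ML2x, -0.39 against 0.06 in ML4x and -0.34 against 0.07 in PL2x. With an estimated correlation camera called none of these. In roots 689 of 1429 root-enriched genes fell and 132 rose in ML2x, 232 and 138 in ML4x, 45 and 38 in PL2x and 319 and 153 in PL4x. Of all genes tested, 39.4%, 14.4%, 3.76% and 18.5% were called in the same order. Median log2 fold changes of the set were -1.31 against 0 for the other genes in ML2x, -0.32 against -0.01 in ML4x, -0.58 against 0.03 in PL2x and -0.66 against 0 in PL4x. Camera's estimated correlation again left none called. In control roots 101 root-enriched genes were lower and 7 higher on the tetraploid than on the diploid rootstock, with a median log2 difference of -0.35 against 0.02 for the other genes (adjusted p = 8e-07 with camera's preset correlation, adjusted p = 0.56 with an estimated correlation). The sets were chosen on these libraries and are not independent evidence.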
